A study of Drosophila melanogaster with 6 samples.

How the data were processed

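The data are peak lists from 3 ChIP-seq libraries of Drosophila melanogaster embryos, made with an antiserum to CrebA in Oregon R and with an antibody to GFP in embryos carrying CrebA-GFP under fkh-Gal4 or sage-Gal4. Each has an input library, so the series has 6 samples. Inputs enter only through the authors' peak calls. Per the labels, embryos were collected over 8 h, aged for 11 h and fixed in 1.8% formaldehyde, with chromatin from 2 collections and a TruSeq ChIP library kit. Whether the collections were pooled before sequencing is not stated in the labels, and each group has 1 library.

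Reads were aligned with BWA to dm6 and peaks were called with MACS2 version 2.1.0.20140616, per the submitters' processing notes; how the inputs entered the calls and the command lines are not given in the sources used here. The deposited lists are in the narrowPeak layout with no header. The fifth column is an integer score by the authors' caller and was not used. The fold enrichment at the summit, a ratio of signal over the caller's local background, was deposited by the authors and used to rank peaks within a list and to correlate the driver lists over SG regions. The deposited lists also give −log10 p and −log10 q per peak, that is, a p-value and a q-value by the authors' caller; the lowest −log10 q was 1.30, 1.31 and 1.31 for fkh-Gal4, sage-Gal4 and Oregon R, close to a q of 0.05. The last column of the deposited lists is the offset of the summit from the peak start, an other unit in bp. The names of peaks carry the word nomodel. Peak lists give no read counts, so the depth and the counting error of each fold are unknown. Differences in list length between libraries can come from depth, antibody or amount of CrebA, and values were not compared between lists as levels.

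Peaks on all sequences were used for overlaps; 7, 13 and 27 peaks lay outside the arms 2L, 2R, 3L, 3R, 4, X and Y. Overlap meant at least 1 bp. SG regions are merged fkh-Gal4 and sage-Gal4 peaks that hold both. Expected overlap came from 1000 circular shifts along each arm, and from peaks moved to random gene ends at the same offset. For the reciprocal and summit rules 100 shifts were drawn.

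Genes were taken from an NCBI RefSeq table of the release 6 assembly, the same assembly as dm6, with 13946 protein-coding genes on the arms. The table used here gives gene start and end without strand, so windows around transcription start sites were replaced by windows of 1000 bp around either end of the gene, and exons and introns were not told apart. The planned search for a CrebA motif at summits needs the genome sequence and was not run. For SG regions the summits used were the strongest fkh-Gal4 and the strongest sage-Gal4 summit of each region.

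The 20 gene lists were fixed before the data were examined, and symbols were matched to current names or to a synonym held by 1 gene. In the COPII list 1 symbol was not matched, and in the trachea list 2 were not. Genes in the text were named by a rule fixed at the same time: the 12 SG regions best ranked by the worse of their ranks in both driver lists, the 6 highest regions of each single-list class, up to 4 bound genes of each gene list with the best such rank and up to 2 unbound in list order, and all transgene loci. Gene lists were tested by two-sided Fisher exact tests against all other protein-coding genes with Benjamini-Hochberg adjustment over 140 tests, and also within the 20 tests of 1 set. Splits of genes bound in 1 of 2 lists were tested against an even split by exact binomial tests. Correlations and differences of heights used 100000 permutations. A threshold of 0.05 on adjusted p was used, and 95% intervals are exact Clopper-Pearson intervals that cover counting error over genes or peaks only.

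The alternatives were a reciprocal overlap of 50%, summits within 150 bp, peaks with a −log10 q of at least 10, the 1000 peaks of highest fold in each list, arms only, random gene ends, gene-end windows of 500 and 2000 bp, assignment to the nearest gene only, a background of genes bound in at least 1 list, and −log10 q in place of fold. For the X chromosome, −log10 p was compared with the large autosomes as a ratio of medians within fold bins of 0.1 holding at least 20 peaks of each, averaged over bins by the number of X peaks. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

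The code was tested on simulated data. For the overlap of driver lists, a simulated list of 6264 peaks with 60% placed on sage-Gal4 peaks gave 62.7%, with 62.7% anticipated from the design of the list, and 2 of 100 unrelated lists passed 0.05. For gene lists over 13946 genes, 38 of 40 lists of 20 genes planted at 85% bound were called, 7 of 40 planted at 50%, and 0 of 100 unchanged lists. For heights, 55 of 1000 unrelated sets of 200 regions passed 0.05 for rho, and 14 of 200 unchanged sets for the rank test.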

Results

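Binding of CrebA, a bZIP transcription factor that raises the expression of secretory pathway genes, was mapped by ChIP-seq in Drosophila melanogaster embryos at stages 11 to 16. There were 3 immunoprecipitated libraries, each with its own input library. In Oregon R embryos, a wild-type strain, endogenous CrebA was precipitated from whole embryos with an antiserum to CrebA. In the other 2, CrebA fused to GFP was expressed from a UAS transgene under fkh-Gal4 or sage-Gal4 and precipitated with an antibody to GFP. Both drivers are active in several tissues, and per the series description the salivary gland (SG) is the only tissue they share. Peaks found with both drivers are called SG regions here, a name that rests on this design. A peak bound in a different tissue with each driver would also be in both lists. The peak lists cannot tell such peaks from those of the gland. Each group has 1 library, so no value has a replicate check. Tests across genes, regions or peaks compare these libraries, and genes and regions are not replicates.

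The authors' peak lists held 6464 peaks for fkh-Gal4, 7916 for sage-Gal4 and 14039 for Oregon R, and covered 3.07%, 3.33% and 7.86% of the chromosome arms. The median peak width was 396, 402 and 478 bp. The median fold enrichment, the authors' own value for each peak, was 1.74, 1.85 and 1.88, and the highest was 3.51, 3.76 and 3.98. Peaks with a −log10 q of at least 10 numbered 1028, 1564 and 5617. Read depth is unknown from peak lists. Fold values are used below to describe and rank peaks within a list, and between lists only in a correlation over shared regions. Coordinates are on dm6.

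The first comparison asked which regions were found with both drivers. The best ranked SG region, X from 934508 to 936812, lay at TRAM, which encodes a protein of the ER translocation channel, with a fold enrichment of 3.51 in the fkh-Gal4 list and 3.47 in the sage-Gal4 list. Next came a region at X from 1859839 to 1862759, at deltaCOP, a subunit of the COPI vesicle coat, and Gcna, with folds of 3.33 and 3.40. Of all fkh-Gal4 peaks, 4874 (75.4%, 95% exact Clopper-Pearson interval 74.3 to 76.4%) overlapped a sage-Gal4 peak by at least 1 bp, and 5019 sage-Gal4 peaks (63.4%, 62.3 to 64.5%) overlapped an fkh-Gal4 peak, giving 4255 SG regions. After 1000 circular shifts of the fkh-Gal4 list along its chromosomes the mean overlap was 6.42%, so that the observed share was 11.8 times higher (one-sided permutation p from the shifts = 0.000999, the smallest that 1000 shifts can give). With peaks moved to random gene ends the mean was 12.9%, and the observed share 5.87 times higher. By deciles of fold enrichment, 99.8% of the highest fkh-Gal4 decile lay in the sage-Gal4 list, with a low of 54.0% in decile 8 and 71.7% in decile 10. With only the 1000 strongest peaks of each list, 53.8% of fkh-Gal4 and 54.3% of sage-Gal4 peaks overlapped the other list, the fkh-Gal4 share being 24.9 times the mean of circular shifts.

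The other 10 best ranked SG regions lay at genes of several functions. A region at 3R from 18627687 to 18628822 lay at CG14301. A pair of regions at X from 7305842 to 7308368 and from 7299307 to 7302117 lay within CG1677, and their nearest gene end was that of brk, a repressor of Dpp target genes, at 1090 and 7840 bp. A region inside jbug, which encodes a filamin-type actin binding protein, had folds of 3.37 and 3.27. Others lay at Gpo1, a mitochondrial glycerophosphate oxidase, with Rif1, a regulator of replication timing, at Brms1 with CG4645, and at PIG-L, an enzyme of GPI anchor synthesis, with psidin. Intragenic regions stood in CrebB, which encodes another bZIP factor, in CG31678 with CG2614 as the nearest gene, and in nvy, a transcriptional corepressor. Of these 12 regions only that in nvy had no Oregon R peak.

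The second comparison asked which genes lie at SG regions. A gene is called bound here when a summit lies within 1000 bp of its start or end coordinate. SG regions bound 3592 of 13946 protein-coding genes (25.8%). The 7 lists of secretory pathway genes fixed before the data were examined held 145 genes, of which 124 (85.5%, exact interval 78.7 to 90.8%) were bound. All 15 genes of the COPI coat and retrieval list were bound, among them deltaCOP (folds 3.33 and 3.40 in fkh-Gal4 and sage-Gal4), garz, which activates the Arf GTPase of this coat (3.16 and 3.05), zetaCOP (2.75 and 2.73) and gammaCOP (2.42 and 2.86).

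ER translocation and signal peptide processing had 22 of 23 genes bound (95.7%), led by TRAM, l(1)G0320 (3.09 and 3.07), a subunit of the translocon-associated complex, Spp, a signal peptide peptidase (2.89 and 3.09), and SrpRalpha, a subunit of the signal recognition particle receptor (3.07 and 2.97). Its unbound gene, Spase25, a signal peptidase subunit, had a sage-Gal4 peak within the window (2.47), but the highest peaks over or beside the gene, with folds of 2.65 and 2.95, had summits 1688 and 1713 bp from the nearest end. COPII vesicles and ER exit also had 22 of 23 bound, including p24-1 and bai, cargo receptors of the p24 family, Sec31, an outer coat subunit, and the SNARE Sec22 (3.28 and 2.86). The unbound gene opm had peaks in each driver list at separate places.

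Golgi tethering and trafficking had 23 of 30 bound (76.7%), among them GM130 (2.70 and 2.96), a golgin, Rab6 (2.25 and 2.38), and the COG complex genes fws and Cog8. Bet5 and Bet3, subunits of a tethering complex, had no peak in either driver list. N-glycosylation and oligosaccharyltransferase had 16 of 21 bound (76.2%): Stt3A, the catalytic subunit (2.62 and 2.68), Ostgamma (2.58 and 2.73), OstDelta and GCS2beta, a glucosidase subunit, were bound, and Dad1 and Alg3 were not. Both Dad1 and Alg3 had a sage-Gal4 summit within the window, at 173 and 78 bp from a gene end. The fws and GCS2beta genes shared 1 peak. ER chaperones and folding had 13 of 16 bound (81.2%), including CG7872, a DnaJ-type protein (2.90 and 3.04), Pdi, the disulfide isomerase (2.72 and 2.92), Grp170 (2.67 and 2.94) and Gp93, the Hsp90 of the ER (2.67 and 3.03). Hsc70-3, the Hsp70 of the ER, was bound in the sage-Gal4 list (2.56) but not by SG regions, as the highest peaks inside the gene, with folds of 2.61 and 3.19, had summits 2569 and 1602 bp from the nearest end. Uggt was bound in the fkh-Gal4 list but not the sage-Gal4 list. O-glycosylation and sulfation had 13 of 17 bound (76.5%), among them pip, a sulfotransferase-like gene of the salivary gland (3.28 and 3.07), the tyrosine sulfotransferase gene Tpst, Pgant6 and Pgant7, while Pgant2 and Pgant4 were unbound.

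All 7 secretory lists were bound more often than other genes by two-sided Fisher exact tests, with Benjamini-Hochberg adjusted p over 140 tests (20 lists in 7 sets) of 1.81e-08 for COPI, 6.34e-11 for ER translocation, 6.34e-11 for COPII, 8.19e-08 for Golgi, 1.54e-05 for N-glycosylation, 4.07e-05 for chaperones and 0.000106 for O-glycosylation. Adjusted over the list alone, that is over the 20 lists of SG regions, they were 7.13e-09, 1.81e-11, 1.81e-11, 3.04e-08, 6.25e-06, 1.53e-05 and 4.33e-05. With the 1000 strongest peaks of each list, 4 of 30 Golgi genes were bound (13.3% against 3.47% of all genes, Fisher exact adjusted p = 0.0747), which ended that call, although the ratio to all genes was 3.84, and 2.98 with all peaks.

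**Figure D1:**
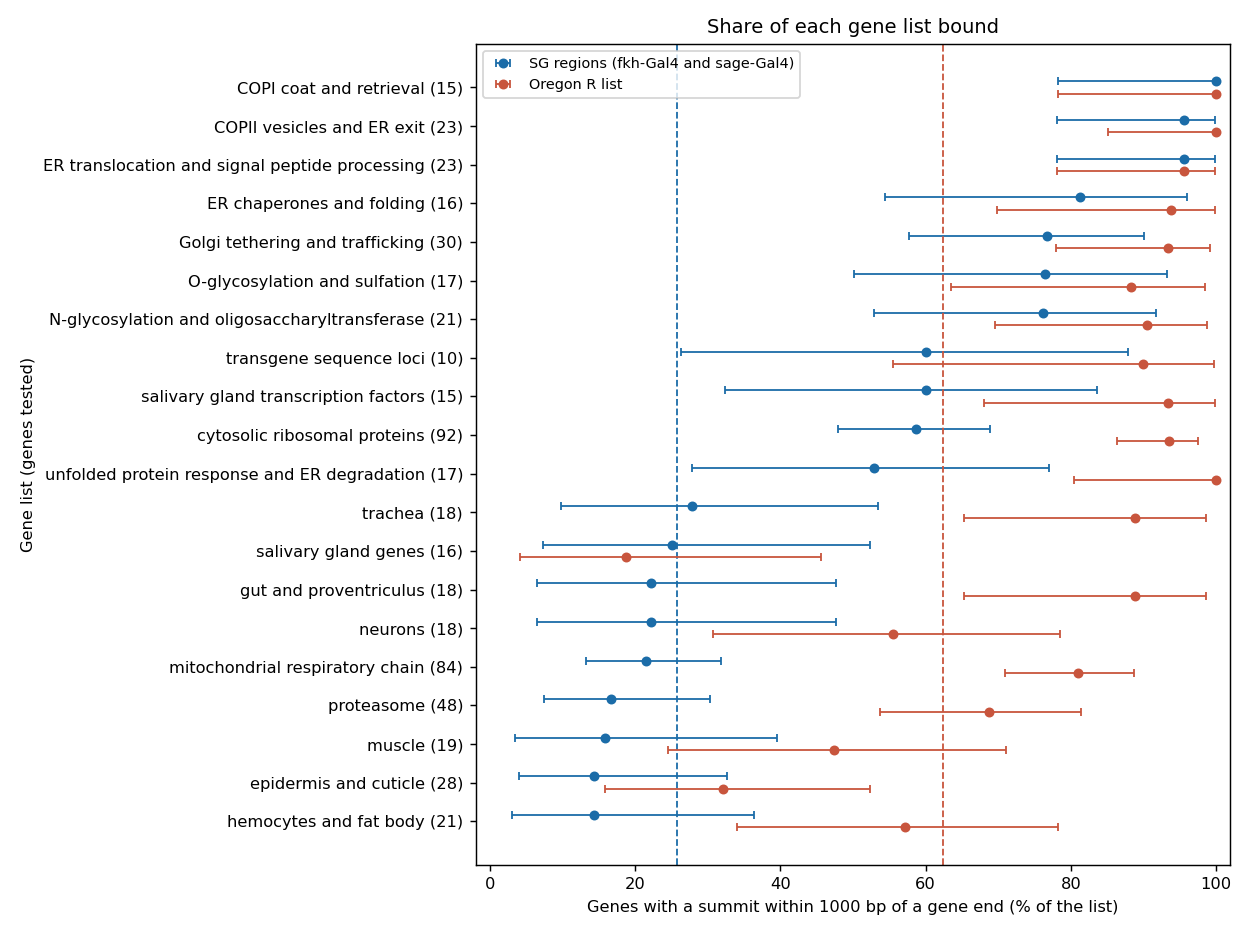
Share of each gene list (percent of the genes tested, their number in brackets) with a summit within 1000 bp of a gene end, for SG regions in blue and the Oregon R list in red. Points are shares, bars 95% exact binomial intervals, and dashed lines the shares over all protein-coding genes, 25.8% for SG regions and 62.4% for Oregon R; the 7 secretory lists lie between 76.2% and 100% for SG regions.

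Genes of the salivary gland itself gave a mixed account. Of 15 transcription factor genes of the gland, 9 were bound (60%, Fisher exact adjusted p = 0.0177; adjusted over the list alone, 0.0115). They included CrebA, fkh, sage and Xbp1, a bZIP factor of the unfolded protein response (2.24 and 2.71), and bowl (2.17 and 2.74). CrebA, fkh and sage are also among the genes described below whose sequences the constructs can carry, and sage had no Oregon R peak. Scr, the homeotic gene that specifies the gland, had no fkh-Gal4 peak within the window, and hth, a homeobox cofactor gene, had none within it in either driver list, though 3 fkh-Gal4 and 7 sage-Gal4 peaks lay elsewhere in the gene. This call ended under 6 of 9 alternatives, for example with 2 of 15 genes bound (13.3% against 5.54% of all genes, Fisher exact adjusted p = 0.467) at a −log10 q of at least 10, where the ratio to all genes was 2.41, and 2.33 with all peaks. The ratio fell to 1.44 with reciprocal overlap, 1.55 with summits within 150 bp and 1.51 with a background of bound genes. Of 16 other salivary gland genes 4 were bound (25%, Fisher exact adjusted p = 1): nur (2.65 and 2.30), PH4alphaSG2, a prolyl hydroxylase subunit (2.31 and 2.20), pip and Papss, which makes the sulfate donor (1.88 and 1.99). The 16 include glue protein genes of the larval gland, such as Sgs3, and no glue gene was among the bound. The 25% is therefore not a share of genes known to be active in the embryonic gland. PH4alphaSG1 had no peak in any list, and ps, which encodes an RNA binding protein, had 11 fkh-Gal4 and 10 sage-Gal4 peaks, none of which made it bound by the SG rule. Unfolded protein response and ER degradation had 9 of 17 bound (52.9%, Fisher exact adjusted p = 0.0611; adjusted over the list alone, 0.0415), among them crc, the ATF4 gene (1.96 and 2.46), Herp (2.21 and 2.38) and Edem1 (1.90 and 2.36). The stress sensor genes Ire1 and Atf6 were unbound by SG regions, though Ire1 was bound in the sage-Gal4 list and Atf6 in the fkh-Gal4 list. The unfolded protein response list passed the threshold with windows of 500 bp (Fisher exact adjusted p = 0.0100) and 2000 bp (0.0219), with the nearest gene only (0.0141), and with regions anywhere in the gene span (0.0192), the last chosen after the data were examined. It did not with the other 5 alternatives (Fisher exact adjusted p from 0.0709 to 0.664).

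Cytosolic ribosomal protein genes were bound at 54 of 92 (58.7%, Fisher exact adjusted p = 3.93e-10), for example RpS20 (2.62 and 2.92) and RpS19a (2.41 and 2.83). RpL10 and RpL10Aa were unbound by SG regions, though RpL10 had a sage-Gal4 summit within the window. The list was matched by a symbol pattern, so it also took in genes named after a ribosomal protein, such as RpL24-like (2.89 and 2.59), which was bound. RpS28b shared its peak with l(1)G0320. With a −log10 q of at least 10, 11 of 92 were bound (12% against 5.54% of all genes, Fisher exact adjusted p = 0.0606), and with the 1000 strongest peaks 6 of 92 (6.52% against 3.47%, 0.362). The ratios to all genes were 2.16 and 1.88, and 2.28 with all peaks.

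The lists of other tissues and functions did not pass the test against other genes in SG regions. Bound were 5 of 18 trachea genes, led by sano (3.0 and 2.81) and ttk, a transcriptional repressor (2.40 and 2.86), with Gasp and sinu named as well. Among gut and proventriculus genes, 4 of 18 were bound, including bowl, dve, wg and hh. In the epidermis and cuticle list 4 of 28 were bound: rtv, grh, a transcription factor of the epidermis, ple, which encodes tyrosine hydroxylase, and kkv, a chitin synthase. For neurons it was 4 of 18 (Appl, elav, Syx1A, unc-13), for muscle 3 of 19 (Mlc2 at 2.67 and 2.81, Mef2, how) and for hemocytes and fat body 3 of 21 (LanB1, crq, LanB2). Named genes unbound by SG regions were trh and btl, drm and odd, ovo and sha, fne and nSyb, Mhc and Mlc1, and Hml and NimC1. Of these, odd and ovo had a sage-Gal4 summit within the window. Proteasome genes were bound at 8 of 48 (Rpt4, Rpt3, Rpn9, Prosbeta5) and mitochondrial respiratory chain genes at 18 of 84 (ATPsyngamma, SdhC, ATPsynG, ND-MNLL), with Prosalpha1, Prosalpha1R, ATPsynB and ATPsynCF6L among the unbound. The lowest Fisher exact adjusted p of these 8 lists was 0.394, for the proteasome, whose genes were bound less often than others when each summit went to the nearest gene only (4.17%, adjusted p = 0.0371).

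The third comparison set the SG regions against binding of endogenous CrebA in whole embryos. Peaks of the secretory genes were also in the Oregon R list: TRAM (fold 3.13), Sec22 (3.85), SrpRalpha (3.17) and garz (3.23) had Oregon R peaks, and 137 of the 145 secretory genes were bound there (94.5%). Of the 4255 SG regions, 3767 overlapped an Oregon R peak (88.5%), compared with 59.7% of the fkh-Gal4 peaks with no sage-Gal4 partner and 80.8% of the sage-Gal4 peaks with no fkh-Gal4 partner (Fisher exact test of SG regions against both pooled, two-sided, p = 1.06e-74). SG regions are merged from peaks of both driver lists, while peaks without a partner were not merged and had lower median folds. Wider or higher peaks can overlap an Oregon R peak more often, and the Fisher test does not account for this. How much of the difference comes from width or height was not tested. For SG regions, circular shifts gave 15.7%, and random gene ends 33.0%. Peaks without a partner were not shifted. With only the 1000 strongest peaks of each list, 29.8% of SG regions overlapped an Oregon R peak. Circular shifts then gave 2.85%, so the observed share was 10.5 times their mean, and 5.63 times with all peaks.

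Merged across the 3 lists there were 15071 regions, of which 3480 (23.1%) were in all 3 and 488 in both driver lists but not in Oregon R. Oregon R shared 446 regions with fkh-Gal4 alone and 1711 with sage-Gal4 alone. Single-list regions numbered 641 for fkh-Gal4, 557 for sage-Gal4 and 7748 for Oregon R (51.4% of all).

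**Figure D2:**
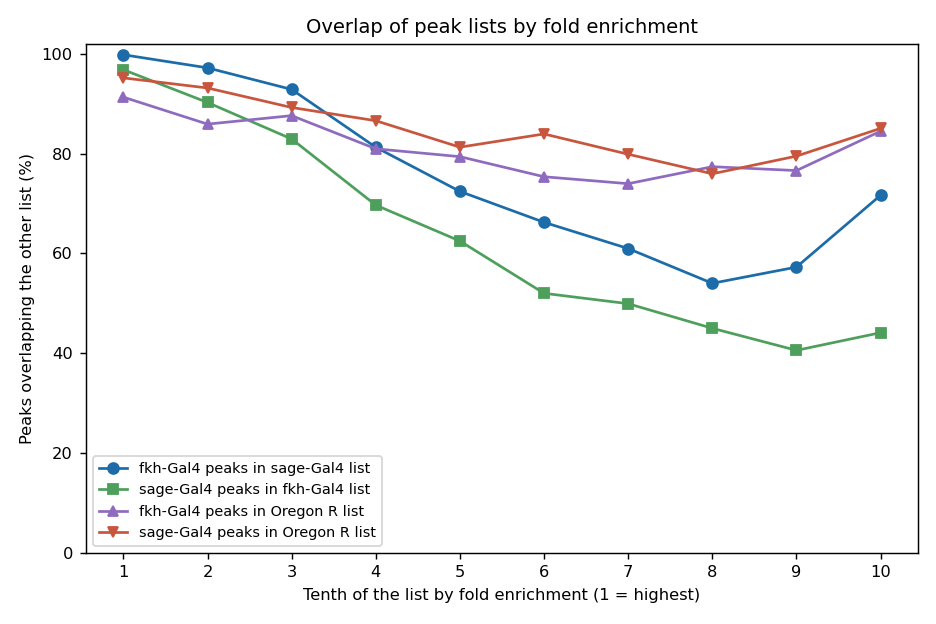
Percent of peaks that overlap another list by at least 1 bp (vertical axis), in deciles of each driver list ordered by the authors' fold enrichment, 1 being the highest (horizontal axis). Each line is 1 pair of lists; the top decile of fkh-Gal4 peaks lay in the sage-Gal4 list at 99.8% and decile 8 at 54.0%.

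The strongest peaks found in 1 list only lay mostly away from gene ends. In the fkh-Gal4 list they had folds of 2.09 to 2.22 and lay nearest to IP3K1, Acp26Aa, which encodes a seminal fluid protein, cad, a homeobox gene of the posterior gut, ed, a cell adhesion gene, Karl and CG42663. In the sage-Gal4 list their folds were 2.30 to 2.61, at Npc2f with Kal1, at CG14431 with Setd3 and CG4586, and nearest to Unc-76, Prat2, scro, a homeobox gene, and CG1607. Those of the Oregon R list reached the highest folds of that list, 3.89 to 3.98. Their nearest gene ends were those of eIF4E4, CG14635, Sp1, a zinc finger factor, CG45691, CG11588 and Ptp99A, a receptor phosphatase. The peaks assigned to CG14635 and CG11588 lay inside CG43867 and CG44837.

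In the Oregon R list 16 of 18 trachea genes and 16 of 18 gut and proventriculus genes were bound, 11 and 12 of them not in SG regions. The Oregon R list is longer, and most genes bound in 1 of the 2 sets leaned this way, with a split of 5274 to 200 for all genes outside the ribosomal protein list. Against other genes within the Oregon R list, neither tissue list passed over all 140 tests (Fisher exact adjusted p = 0.0676 for each; adjusted over the list alone, 0.0365). Gut genes were found more often at regions of the Oregon R list only (14 of 18, Fisher exact adjusted p = 0.00296), as were respiratory chain genes (46 of 84, adjusted p = 0.00251). Some of these genes also had driver peaks. Found less often there were ER translocation genes (2 of 23, Fisher exact adjusted p = 0.0148), salivary gland genes (0 of 16, 0.00406) and epidermis genes (4 of 28, 0.0498). Regions of the Oregon R list only overlap no driver peak by definition, and SG regions bound 22 of 23 ER translocation genes. The low count of ER translocation genes is therefore not independent of that binding. At regions of the fkh-Gal4 list only, Golgi genes (4 of 30, Fisher exact adjusted p = 0.00359) and transgene loci (2 of 10, 0.0277) were found more often. All 23 Golgi genes and all 6 transgene loci bound in the fkh-Gal4 list were also bound in the sage-Gal4 list. These were thus further peaks at genes bound with both drivers. Epidermis and cuticle genes were bound less often than other genes in the Oregon R list (9 of 28, Fisher exact adjusted p = 0.00535), and so were salivary gland genes (3 of 16, adjusted p = 0.00218), a list that includes the glue protein genes of the larval gland and of which nur and PH4alphaSG2 had driver peaks and no Oregon R peak within the window.

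Peak heights of the drivers were related over the 4255 SG regions, with Spearman's rho of 0.543 and Pearson's r of 0.584 between fold enrichments (permutation p for rho = 1e-05, the smallest that 100000 permutations can give). Peaks shared with the other driver were higher than those that were not, with median folds of 1.80 against 1.64 in the fkh-Gal4 list and 1.99 against 1.73 in the sage-Gal4 list (permutation tests, two-sided, p = 1e-05 for each). With a −log10 q of at least 10, rho was 0.380 and these medians were 2.36 against 2.34 (permutation p = 0.00961) and 2.54 against 2.40 (permutation p = 1e-05).

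SG regions lay near gene ends more often than random positions, with 54.4% of strongest summits within 1000 bp of a gene end against 24.2% of 100000 random positions. A further 38.6% lay inside a gene farther from its ends, and 7.06% between genes. The share near gene ends was 41.9% for fkh-Gal4 peaks without a partner (Fisher exact test against SG regions, adjusted p = 1.0e-16), 58.6% for sage-Gal4 peaks without a partner (0.000389) and 50.7% for regions of the Oregon R list only (0.000231). With a −log10 q of at least 10 the order of SG regions and regions of the Oregon R list only was reversed, at 57.0% against 69.4%. All 3 lists were cut first, to 1028, 1564 and 5617 peaks for fkh-Gal4, sage-Gal4 and Oregon R. Regions of the Oregon R list only can then include regions whose driver peaks fell below the cut.

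Genes whose sequences driver and UAS constructs can carry were described for each list. Within 1000 bp of CrebA, at 3L from 15535395 to 15553214, there were 7 fkh-Gal4, 5 sage-Gal4 and 6 Oregon R peaks. The highest of the driver peaks lay inside the gene, from 15548345 to 15550584 in fkh-Gal4 (fold 2.34) and from 15548346 to 15550037 in sage-Gal4 (2.70). The highest Oregon R peak lay beyond the end of the gene, from 15553789 to 15554901 (2.19). At sage, a bHLH factor gene of the salivary gland at 3R from 9262654 to 9264142, both driver lists had peaks, with folds of 1.95 in fkh-Gal4 and 2.02 in sage-Gal4, and Oregon R had 0. At fkh, a forkhead factor gene, folds were 1.91, 2.81 and 2.60, and at w, the eye colour marker, 1.58, 1.70 and 3.09. The heat shock genes Hsp70Aa, Hsp70Ab, Hsp70Ba and Hsp70Bc had peaks in the sage-Gal4 and Oregon R lists and none in the fkh-Gal4 list, while the neighbours Hsp70Bb and Hsp70Bbb had peaks in all 3. As a list these 10 genes had 6 bound by SG regions (60%, Fisher exact adjusted p = 0.0638; adjusted over the list alone, 0.0415).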

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

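The comparisons of secretory genes with broadly expressed and with highly transcribed genes, the split of other genes at equal list length and the test of the top decile of peaks on the X were chosen after the results were seen; the other tests below on these 3 patterns were written down before.

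Ribosomal protein genes differed between the driver lists: 27 were bound in the sage-Gal4 list alone and 1 in the fkh-Gal4 list alone (exact binomial p against an even split = 2.16e-07, adjusted over 20 lists 4.32e-06). No other gene list differed at an adjusted p under 0.05, but most had too few genes bound in 1 driver list only to pass on their own. With the sage-Gal4 list shortened to 6464 peaks the split was 25 to 5 (exact binomial p = 0.000325), which argues against list length as the whole source. Other protein-coding genes leaned the same way, with 1744 of 2050 discordant genes bound in the sage-Gal4 list (85.1% against 96.4% for ribosomal protein genes, Fisher exact p = 0.109) and 1351 to 479 at equal length (Fisher exact p = 0.297), so a shift shared by all genes stays open. Highly transcribed genes outside the ribosome, such as eEF2 and Act5C, were bound in the sage-Gal4 list at 21 of 24 (87.5%). There they were not told apart from ribosomal protein genes (Fisher exact p = 0.711) and lay above all genes (Fisher exact p = 1.22e-06). In the fkh-Gal4 list they were bound at 16 of 24 (66.7%), and ribosomal protein genes at 57 of 92 (62.0%). The test covers the sage-Gal4 list alone and not the difference between drivers. Signal at highly transcribed genes may contribute, and a difference between the tissues of the drivers is untested.

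For the binding of secretory genes in SG regions, random lists matched on gene-end density and gene length were bound at 29.2% on average, and none of 10000 reached the 124 of 145 secretory genes (share 0.0001, the smallest they can give). Density and length therefore do not account for the binding alone. The 7 lists taken as broadly expressed genes outside the secretory pathway held 398 genes, of which 176 were bound (44.2%, exact interval 39.3 to 49.3%). This was below the secretory genes (Fisher exact p = 5.43e-19). No expression values were used to choose these lists, and their shares ran from 16.7% for proteasome genes to 72.7% for initiation factors. Broad expression as a source was therefore not settled. Highly transcribed genes outside the ribosome were bound at 15 of 24 (62.5%), below the secretory genes (Fisher exact p = 0.0169). They were not chosen by transcription in the driver tissues, so this cannot decide whether signal at highly transcribed genes is the whole source. These 24 genes lay above all genes, as did ribosomal protein genes (58.7%) and initiation factors (72.7%, not told apart from the secretory genes, Fisher exact p = 0.0684). By rank of fold, 52.0% of bound secretory genes had a peak in the top decile of the fkh-Gal4 list, against 12.3% of bound ribosomal protein genes. In the sage-Gal4 list the shares were 43.1% and 16.9%. This comparison does not cover the other lists, and a contribution of such signal stays open. Whether the gland differs from other tissues in this was not tested, and 137 of the 145 genes were also bound in the Oregon R list.

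The X chromosome took a share of peaks that rose with fold enrichment in each list. It held 28.1%, 29.4% and 32.9% of the top decile of the fkh-Gal4, sage-Gal4 and Oregon R lists, against 20.4%, 17.1% and 14.1% of deciles 4 to 7 (largest of 3 Fisher exact p = 3.37e-05). The rise was thus not confined to the lowest deciles. These deciles were compared after the rise was seen, so this is no separate test of weak X peaks missing near the threshold. Among peaks over 1000 bp from a gene end the excess held (largest Fisher exact p = 0.00122), which argues against closeness to genes. At equal fold, the −log10 p on the X was 0.871 to 0.882 times that on the large autosomes, so a lower read depth on the X, as in embryos of which some are male, may widen its spread of folds. A biological difference of CrebA binding on the X was not tested.

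Over whole lists the X held 19.1% of fkh-Gal4 and 17.8% of sage-Gal4 peaks against 16.1% of Oregon R peaks (Fisher exact adjusted p = 1.04e-06 and 0.00721 over 21 tests). Chromosome 4 held 0.557% of fkh-Gal4 and 0.354% of sage-Gal4 peaks against 2.09% of Oregon R peaks (Fisher exact adjusted p = 9.28e-18 and 8.85e-29). Outside the chromosome arms, on sequences that no comparison of gene lists uses, there were 7 fkh-Gal4, 13 sage-Gal4 and 27 Oregon R peaks.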

How the results depend on the processing

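Reciprocal overlap for gene lists and regions anywhere in the gene span were chosen after the data were examined; the other alternatives were set before. Of 207 alternative values 168 kept their direction and their side of the threshold. For the salivary gland transcription factors the call ended with reciprocal overlap (26.7% bound), summits within 150 bp (33.3%), a −log10 q of at least 10 (13.3%), the 1000 strongest peaks (13.3%), a window of 2000 bp (60%) and a background of bound genes (60%). Ribosomal protein genes lost their call at a −log10 q of at least 10 (12%) and with the 1000 strongest peaks (6.52%), and Golgi genes with the latter (13.3%). The share of all genes fell as well with these 2 settings, to 5.54% and 3.47%, and ratios to it were 2.16 and 1.88 for ribosomal protein genes (2.28 with all peaks), 3.84 for Golgi genes (2.98) and 2.41 and 3.84 for the transcription factors (2.33), whose ratio was lower under the other 4 alternatives that ended the call (1.44, 1.55, 1.88 and 1.51). The unfolded protein response list passed with windows of 500 bp (52.9%) and 2000 bp (64.7%), the nearest gene only (47.1%) and the gene span (64.7%), and proteasome genes were bound less often than others with the nearest gene only (4.17%). In 22 cases a list that passed the threshold neither way moved to the other side of the genes outside it. These were salivary gland genes with reciprocal overlap (18.8%), a −log10 q of at least 10 and the 1000 strongest peaks (6.25% each), a window of 500 bp and the nearest gene only (25% each), a background of bound genes (80%) and the gene span (31.2%). Others were gut genes with a −log10 q of at least 10 and the 1000 strongest peaks (5.56% each), a window of 2000 bp and the gene span (33.3% each), and muscle genes (10.5% each) and transgene loci (0% each) with the 2 stricter peak sets. Neurons did so with summits within 150 bp (22.2%), a −log10 q of at least 10 (5.56%) and a background of bound genes (40%), trachea genes with a window of 2000 bp (27.8%) and that background (31.2%), epidermis genes with that background (44.4%) and respiratory chain genes with reciprocal overlap (19.0%). Genes at SG regions fell from 3592 to 772 at a −log10 q of at least 10 and to 484 with the 1000 strongest peaks, by construction, since fewer peaks enter. The share of SG regions near gene ends was below that of regions of the Oregon R list only at a −log10 q of at least 10 (57.0%), with both classes redrawn from the cut lists. Apart from those counts, the cause was not tested. Overlap of the drivers ranged from 46.4% to 75.4% of fkh-Gal4 peaks, and of SG regions with Oregon R from 29.8% to 88.5%. The 29.8% came with the 1000 strongest peaks of each list, where circular shifts gave 2.85%. Peak lists give no depth, so weak peaks missing from a shallower library cannot be counted. Alternatives on the CrebA motif were not run, as they need the genome sequence. No paired analysis was possible because each group has 1 library.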

Other observations

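The gene families below were listed after the lists were opened and before their counts were seen, and the counts of tRNA genes and of SNARE genes outside the secretory lists, and the removal of genes whose symbols match a family they are not in (Cyp1, Cyp40, Cpr, Rab3-GAP, Rab3GAP1, Rab3-GEF, Snapin), were chosen after the results were seen; Fisher exact tests are two-sided and adjusted over 52 tests. Translation initiation factors were bound by SG regions at 32 of 44 genes (72.7%, exact adjusted p = 4.57e-10), among them eIF1, eIF2alpha and eIF4A. Aminoacyl-tRNA synthetases, which charge tRNAs, followed with 18 of 33 (54.5%, exact adjusted p = 0.000834), for example AlaRS, LysRS and TyrRS. Rab genes, which direct vesicle traffic and some of which the Golgi list also holds, had 19 of 33 bound (57.6%, exact adjusted p = 0.000317), and subunits of the V-ATPase, the proton pump of acidic organelles, 16 of 33 (48.5%, exact adjusted p = 0.0071). Of SNARE genes 12 of 23 were bound (52.2%, exact adjusted p = 0.00964), but 9 of these are in the secretory lists, and outside those lists 3 of 14 were bound (21.4%, Fisher exact adjusted p = 1 over 13 tests). Mitochondrial ribosomal proteins had 31 of 73 in SG regions (42.5%, exact adjusted p = 0.00302) and 71 of 73 in the Oregon R list (97.3%, exact adjusted p = 7.4e-12). Highly transcribed genes outside the ribosome had 15 of 24 (62.5%, exact adjusted p = 0.000317). Of 20 bZIP factor genes 9 were bound (45.0%, exact adjusted p = 0.0782), CrebA, CrebB, Xbp1 and crc among them.

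Several families were bound less often than other genes in SG regions. Chemoreceptor genes had 7 of 179 bound (3.91%, exact adjusted p = 7.04e-14), cuticular protein genes 2 of 121 (1.65%, exact adjusted p = 1.55e-12), cytochrome P450 genes 4 of 83 (4.82%, exact adjusted p = 2.82e-06) and odorant binding protein genes 2 of 51 (3.92%, exact adjusted p = 0.000173). None of the 8 chorion and vitelline genes was bound (exact adjusted p = 0.133). The tests take genes as independent, so they overstate the evidence where members of a family lie close together. Random lists matched on gene-end density and gene length were not drawn for these families.

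SG regions with no Oregon R peak numbered 488. The best ranked lay in nvy (folds 3.48 and 3.13), nearest to mIF2 (2.98 and 3.26), in CrzR, the corazonin receptor gene (2.73 and 2.94), in DIP-kappa (3.09 and 2.83), nearest to CG12290 (2.64 and 2.83) and in Tpst (3.07 and 2.81). They bound 114 genes, of which sage, nur, PH4alphaSG2, C1GalTA and sll were in the gland, O-glycosylation or sulfation lists; no list passed (lowest exact adjusted p = 0.0831).

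Transfer RNA genes differed between the drivers. Of 290 tRNA genes, 53 were bound in the fkh-Gal4 list (18.3%), 147 in the sage-Gal4 list (50.7%) and 214 in the Oregon R list (73.8%). Of the 106 bound in 1 driver list only, 100 were in the sage-Gal4 list. With the sage-Gal4 list shortened to equal length the split was 80 to 10, compared with 1351 to 479 for protein-coding genes outside the ribosome (Fisher exact p = 0.00076). tRNA genes lie in clusters that share peaks, with 40 fkh-Gal4 and 73 sage-Gal4 peaks near them at equal length, so these tests overstate the evidence.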
